A study of Mus musculus with 8 samples.

How the data were processed

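RNA was taken from neural progenitor cells isolated by sorting from dissociated mouse neural tubes at embryonic day 14, in 4 libraries labelled 53BP1 KO and 4 labelled control. Libraries were made with a stranded total RNA kit and sequenced as paired ends on either of 2 Illumina HiSeq models, per the labels' protocols, which do not say which model was used for which library or whether the cells of a library were taken directly or after culture in differentiation medium. The knockout embryos came from crosses of females with a targeted Trp53bp1 allele and males with in-frame deletions made by CRISPR, per the labels' protocols.

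The deposited values are whole-number counts of reads per gene. The submitters' processing notes name CASAVA, HTSeq 0.6.1p1 and the mouse builds mm9 and NCBIM37; the aligner and the strand setting of the counting are not given in the sources used here. The deposited table of counts held 32499 genes, of which 1991 had a count of 0 in every library. Chromosomes and neighbouring genes were taken from the RefSeq and GENCODE tables of GRCm38 by symbol, with no coordinates, since the counts were made on another assembly. A chromosome was found for 97% of the genes tested. All genes were given by symbol. Antisense and overlapping genes, near-identical paralogs and histone genes may share reads.

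Library depth was between 11081419 and 24339621 counts. No pair of libraries within a group agreed within sampling noise: a chi-square test over genes with a sum of at least 10 counts gave between 4.85 (controls 2 and 3) and 41.1 per degree of freedom, so all libraries were kept as replicates. The 5 most abundant RNAs (Rpph1, Malat1, Rmrp, Gm26917 and Gm10800) took 9.27% ± 0.473 of the counts in the controls and 9.93% ± 1.01 in the KO-labelled libraries (SD, n = 4). Gm10800 alone ran from 0.145% in KO-labelled 1 to 2.92% in control 2. The number of genes with any count was also lowest in KO-labelled 1 (19493) and highest in control 2 (27166).

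Genes were kept by filterByExpr, scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 without robust dispersion, in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05; 15021 genes were tested. CPM are counts scaled to TMM-adjusted library size. The SE of a log2 fold change is its size divided by the square root of the F statistic of the same test. It can understate the error where a group has few counts. Where a group had 0 counts, the fold was set against a floor of 3 counts per library, which covers counting error only. Camera from limma 3.58.1 with a preset correlation of 0.01 between genes tested each of 26 lists with at least 5 tested members, adjusted over the lists. An estimated correlation and fry were run beside it. The 29 lists, the tests and the alternatives were fixed before the data were examined. They are progenitor, proneural, neuronal, GABAergic, glutamatergic, Hox, forebrain and midbrain, spinal cord, astrocyte, oligodendrocyte, G1/S, G2/M, p53 target, double-strand break repair, H3K27 and UTX, interferon, immediate early, erythroid, microglial, endothelial, mesenchymal, neural crest, muscle, cartilage, choroid plexus, sex-linked, mitochondrial, ribosomal protein and histone genes.

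The rule for named genes was also fixed beforehand. It takes Trp53bp1 and Kdm6a, the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 5 CPM in the higher group and no overlap between the groups, without predicted names, and up to 4 members past the threshold per list, or the 2 most abundant where none passed. The text names a part of these, and some genes that the rule takes are not reported here. Fabp7, Mt3, Fam35a, Mad2l2, Xrcc5 and the genes named from the 6 lists below stand outside the rule, except where it also takes them. They were chosen after their values were seen. A further 6 lists (ATF4 targets, cytosolic aminoacyl-tRNA synthetases, endoplasmic reticulum chaperones, glycolysis and hypoxia, cholesterol biosynthesis, X-inactivation escape genes) were written after the gene results had been seen in part.

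The fit was tested on simulated counts for the comparison of the KO-labelled with the control libraries, with 200 of 14753 genes changed. It recovered 46.9% of the genes changed by 1.5-fold and 78.6% of those changed by 2-fold, with 4.65% false calls among all calls and a bias of the median log2 fold change of at most 0.02. A recovery of at least 80% at 2-fold had first been required; it was not met, the missed genes were of low count, and the requirement was replaced by limits on bias and false calls. The simulation changed a far smaller share of genes than the 4499 of 15021 called in the data. The adjusted threshold depends on that share, so the recovery in the data may differ from these values. Smaller changes could still be missed.

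Alternatives were DESeq2 1.42.0, limma voom with quality weights, robust dispersion, RLE and upper-quartile scaling, other filters on low counts, each library left out, a replicate block, removal of sex-linked genes and an Xist covariate. Added after the data were seen were the removal of chromosomes X and Y, offsets for GC content and transcript length from smooth fits with mgcv 1.9.3, and a covariate of olfactory and vomeronasal receptor counts.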

Results

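Gene expression was measured by RNA-seq in neural progenitor cells of the mouse neural tube at embryonic day 14. The cells were sorted with NeuroFluor CDr3, a fluorescent dye that binds Fabp7, a fatty acid binding protein of radial glia. There were 8 libraries in 2 groups, 4 labelled as 53BP1 knockout (KO-labelled below) and 4 labelled as control. 53BP1, encoded by Trp53bp1, is a chromatin protein best known for its part in the repair of DNA double-strand breaks. The total count was between 15343046 and 18189045 reads in the control libraries and between 11081419 and 24339621 reads in the KO-labelled libraries. A gene with 3 counts had a normalised read count between 0.126 and 0.261 CPM, depending on the library. The labels do not say that the replicates came from separate embryos or cultures, so p-values measure only the spread between these libraries, which may be technical.

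The comparison asks how the transcriptome of neural progenitors differs between 53BP1 KO and wild-type embryos, with Kdm6a, which encodes the H3K27 demethylase UTX, as a second gene of interest in the design. The targeted gene did not separate the groups. Trp53bp1, on chromosome 2, had 26.8 ± 0.35 CPM in the controls and 27.1 ± 6.36 CPM in the KO-labelled libraries (SD, n = 4 each). Its log2 fold change was 0.01 (SE 0.14, 95% interval -0.27 to 0.29, adjusted p = 0.96 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Per library it had 497, 487, 417 and 412 counts in the controls and 617, 388, 341 and 600 counts in the KO-labelled libraries. The alleles included in-frame deletions, per the labels' protocols, which need not lower the count of a whole gene, so this level neither supports nor contradicts the labels. Kdm6a, on the X chromosome, fell from 39.5 ± 3.80 to 22.9 ± 3.67 CPM, a log2 fold change of -0.79 (SE 0.12, adjusted p = 0.000217 by edgeR), and all 4 KO-labelled libraries lay below all 4 controls.

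The groups also differed in the genes that tell the sexes apart. Xist, the RNA that coats the inactive X chromosome of female cells, had between 23853 and 26134 counts in the controls and between 9 and 16 counts in the KO-labelled libraries. Ddx3y, on the Y chromosome, had 0 counts in every control and between 579 and 1064 counts in the KO-labelled libraries, at least 265-fold higher against a floor of 3 counts per library. Eif2s3y and Kdm5d, also Y-linked, each had 2 counts in all controls together and 7389 and 2453 counts in the KO-labelled libraries. Uty, the Y-linked relative of Kdm6a, rose from 0.84 ± 0.399 to 25.4 ± 2.29 CPM (log2 fold change 4.90, SE 0.22, adjusted p = 1.31e-09 by edgeR). Of the 5 sex-linked genes tested, 4 rose and 1 fell, and the counts were the same when adjusted over the list alone (camera adjusted p = 8.2e-26, Up, and adjusted p = 0.00379 with an estimated correlation). Every control library thus had the expression of female cells and every KO-labelled library that of male cells, and group and sex coincided in 8 of 8 libraries. No difference reported here can be assigned to the 53BP1 genotype apart from sex.

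**Figure D1:**
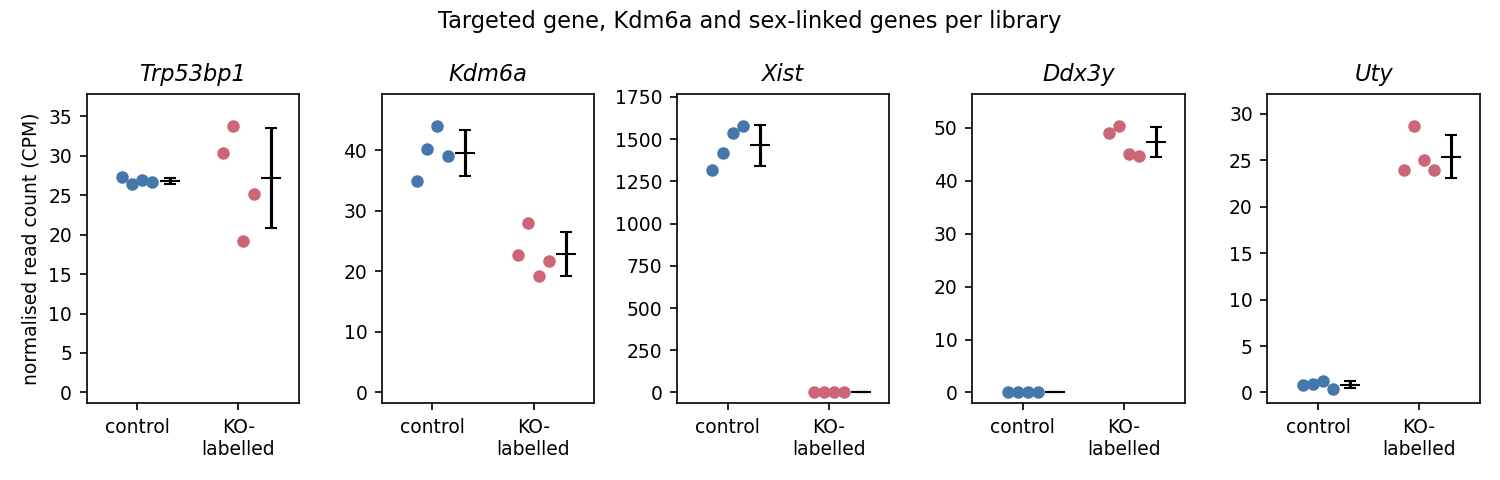
Normalised read count (CPM, y axis) of Trp53bp1, Kdm6a, Xist, Ddx3y and Uty in the control and KO-labelled libraries. Each point is a library and the bars are the mean ± SD of 4; Trp53bp1 overlapped between groups, Kdm6a was lower in all KO-labelled libraries, and Xist against Ddx3y and Uty split the libraries completely.

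Beyond the sex-linked genes, the largest rises in the KO-labelled libraries were in Adm2, Cox6a2, Fgf21, Trib3, Chac1, Fibin and P2rx3. Trib3, Chac1, Fibin and P2rx3 lie on chromosome 2, as does Trp53bp1, and Adm2, Cox6a2 and Fgf21 lie on other chromosomes. Chromosome 2 held 1187 of the 15021 genes tested. Trib3, a pseudokinase, rose from 3.89 ± 2.09 to 251.6 ± 28.3 CPM (log2 fold change 6.03, SE 0.25, adjusted p = 6.75e-10 by edgeR), and Chac1, which degrades glutathione, rose from 7.22 ± 3.24 to 238.3 ± 23.3 CPM (5.05, SE 0.22). The secreted factors Adm2 and Fgf21 rose by log2 fold changes of 7.36 (SE 0.22) and 6.28 (SE 0.28) from 0.133 ± 0.0664 and 0.279 ± 0.189 CPM. Cox6a2, a subunit of cytochrome c oxidase, rose by 7.16 (SE 0.28), Fibin by 4.99 (SE 0.27) and P2rx3, an ATP-gated channel, by 4.97 (SE 0.22). Adm2, Fgf21 and Cox6a2 had 9, 19 and 13 counts in all controls together, so their folds are less certain than these SE state. The largest falls after Xist were in the X-linked gene Fndc3c1 (-3.01, SE 0.18), the matrix gene Ogn (-2.89, SE 0.32) and the forebrain transcription factors Lhx2 (-2.81, SE 0.22) and Dmrta2 (-2.46, SE 0.17). Lix1 (-2.46), Col6a3 (-2.40), Nrn1 (-2.17), the S phase cyclin Ccne2 (-2.15) and Epb41l4a (-2.09) completed the 10 largest falls, all with complete separation of the groups.

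Of 15021 genes tested, 2412 rose and 2087 fell in the KO-labelled libraries, or 4499 in all, and 594 rose and 405 fell by more than 2-fold. The groups did not overlap for 29.9% of the genes, where chance gives 2.86%. On the autosomes 30.3% of the genes passed the test and on the X chromosome 33.2% (Fisher's exact test, two-sided, p = 0.165). The genes that passed leaned lower on the X chromosome, where 41.0% of them rose against 54.1% on the autosomes (odds ratio 1.70, Fisher's exact p = 0.000703). The first principal component carried 53.9% of the variance and separated the groups.

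**Figure D2:**
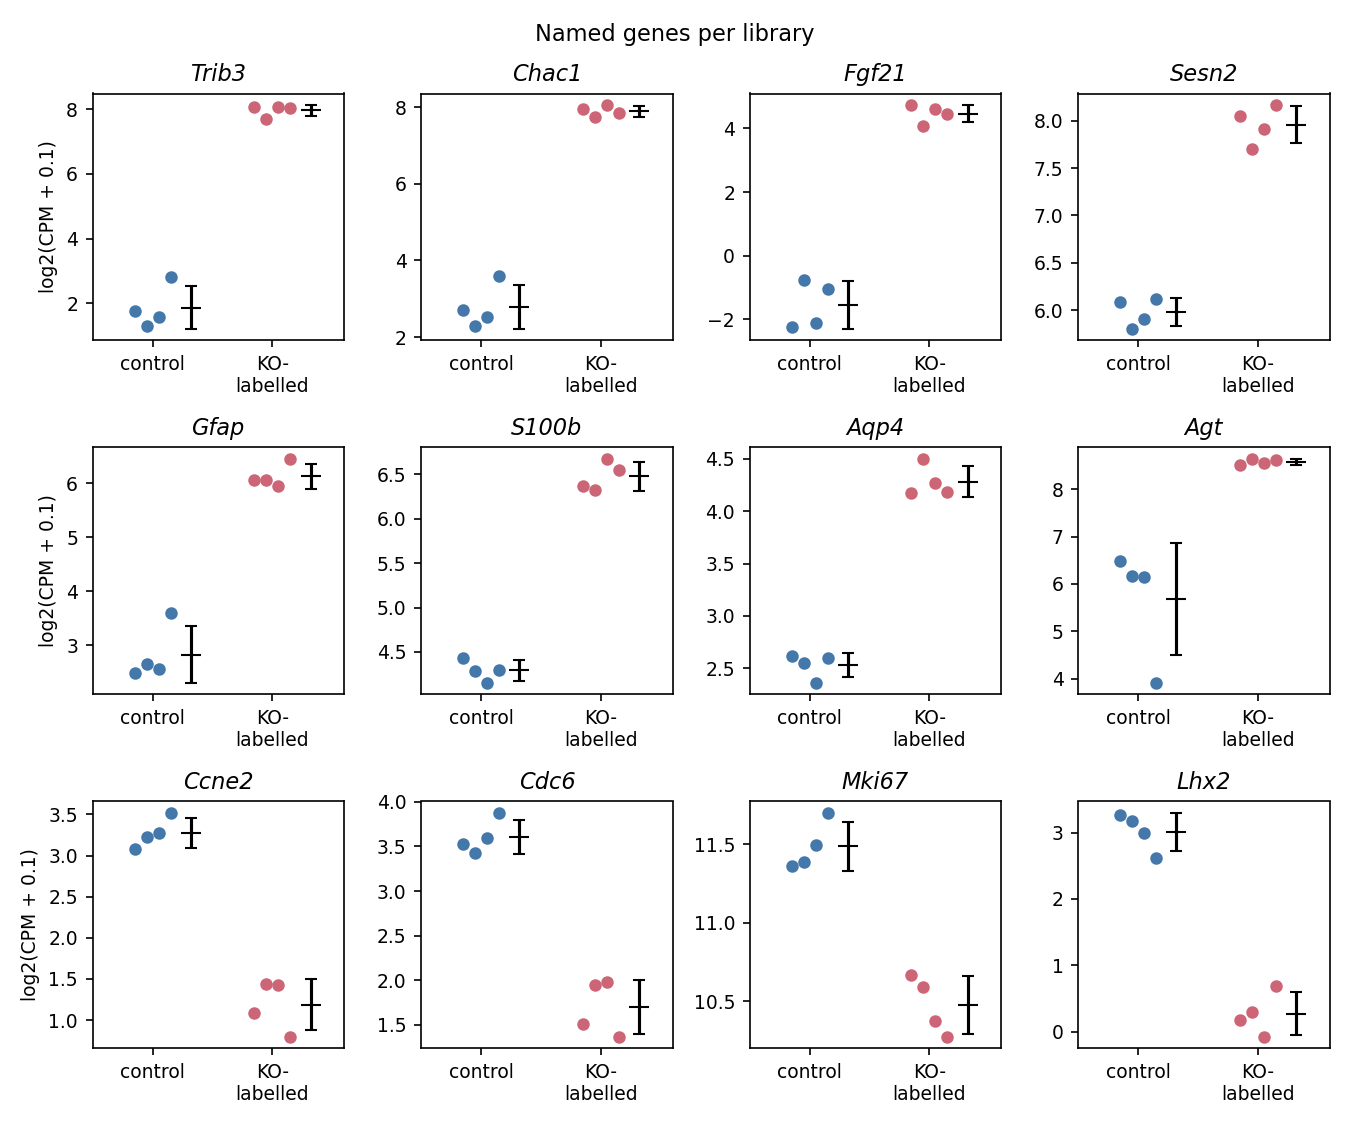
Expression of 12 named genes, as log2(CPM + 0.1) on the y axis, in the control and KO-labelled libraries. Each point is a library and the bars are the mean ± SD of 4; the genes of the upper and middle panels were higher, and those of the lower panels lower, in every KO-labelled library.

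Astrocyte genes rose together. Of 17 tested, 13 rose and 1 fell, and 13 rose and 1 fell when adjusted over the list alone (median log2 fold change 0.68, camera adjusted p = 1.46e-10, and adjusted p = 0.00992 with an estimated correlation). Gfap, the intermediate filament of astrocytes, rose from 7.41 ± 3.14 to 70.6 ± 11.7 CPM (3.26, SE 0.22), S100b from 19.5 ± 1.56 to 89.5 ± 10.2 CPM (2.20, SE 0.11) and the water channel Aqp4 from 5.69 ± 0.455 to 19.5 ± 2.14 CPM (1.77, SE 0.13). Agt, the angiotensin precursor, rose from 61.9 ± 32.4 to 382.3 ± 16.8 CPM (2.62, SE 0.35), and Mt3 was the member that fell (-0.49); its call was lost without control 1, KO-labelled 1 or KO-labelled 2. Oligodendrocyte lineage genes did not pass as a list (camera adjusted p = 0.133), although 7 of 14 rose and 2 fell, with the same counts adjusted over the list alone. Among them were the myelin gene Mbp (1.14, SE 0.16) and the transcription factor Sox8 (0.74, SE 0.12). The list passed when control 4 was left out, without a filter on low counts and with voom.

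The progenitor genes moved both ways. Of 20 tested, 9 rose and 3 fell, or 9 and 4 adjusted over the list alone, and the list did not pass (median 0.23, or 0.15 without KO-labelled 4, camera adjusted p = 0.157). The transcription factor Sox2 rose from 97.0 ± 7.68 to 166.3 ± 22.7 CPM (0.78, SE 0.10), Msi1 rose by 0.87 (SE 0.14) and the matrix protein gene Tnc by 0.71 (SE 0.11), whereas the intermediate filament gene Nes fell from 212.9 ± 37.2 to 113.9 ± 16.8 CPM (-0.90, SE 0.13). Fabp7, whose protein the dye binds, had a log2 fold change of 0.04 (SE 0.13, adjusted p = 0.85 by edgeR). Of 12 proneural genes 1 rose and 3 fell, the same adjusted over the list alone, with Neurod1 among those that fell (-2.40, SE 0.38), and the list did not pass (adjusted p = 0.358). Of 26 genes of neuronal differentiation 4 rose and 5 fell, the same adjusted over the list alone (adjusted p = 0.583), and Snap25 (-1.16, SE 0.22) and Syt1 (-0.83, SE 0.15), both of the synaptic vesicle machinery, were among those that fell. The 4 rises became 1 without control 2, control 3, KO-labelled 1 or KO-labelled 4, 2 without control 1 or KO-labelled 2 and 6 without control 4, and the 5 falls became 3 without KO-labelled 4.

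Cell cycle genes were lower in the KO-labelled libraries. All 24 genes of the G1/S list fell, also adjusted over the list alone (median -1.07, camera adjusted p = 3.35e-26, and adjusted p = 0.168 with an estimated correlation). Ccne2 fell from 9.64 ± 1.28 to 2.22 ± 0.475 CPM, and Cdc6 (-1.95, SE 0.17) and Cdt1 (-1.70, SE 0.18), which load the replicative helicase, fell with it. Of 25 genes of the G2/M list 23 fell, or 24 adjusted over the list alone (median -0.54, camera adjusted p = 7.21e-11, and adjusted p = 0.241 with an estimated correlation). Mki67, the gene of the proliferation marker Ki-67, fell from 2881 ± 318 to 1431 ± 180.2 CPM (-1.01, SE 0.11) and Cdk1 by -0.81 (SE 0.11). Of 15 replication-dependent histone genes 7 fell, or 8 adjusted over the list alone (median -0.32, camera adjusted p = 0.00227, and adjusted p = 0.583 with an estimated correlation), led by Hist1h1b (-1.32, SE 0.12); without KO-labelled 3 the number that fell was 11 and the median -0.52. These histone genes are near copies of one another, and the count of a member depends on how shared reads were treated.

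Genes of double-strand break repair, the process in which 53BP1 acts, were also lower as a list. Of 32 tested, 17 fell and 3 rose, or 20 and 3 adjusted over the list alone (median -0.36, camera adjusted p = 4.45e-05, and adjusted p = 0.241 with an estimated correlation). Exo1, a resection nuclease, fell from 65.7 ± 10.9 to 19.4 ± 1.90 CPM (-1.76, SE 0.13), and Brca1 (-1.34, SE 0.14), Polq (-1.27, SE 0.17) and Palb2 (-0.99, SE 0.17) fell too. The 3 rises, Fam35a (0.46), Mad2l2 (0.35) and Xrcc5 (0.32), became 1 without control 2, control 3 or KO-labelled 4. The list mixes several routes of repair and was not split by route. Whether its fall follows that of the cell cycle genes was not tested. Of 29 p53 targets 16 fell and 4 rose, or 20 and 4 adjusted over the list alone (median -0.49, camera adjusted p = 0.00711, and adjusted p = 0.583 with an estimated correlation). Ddit4l (-0.94, SE 0.15) and the death receptor gene Tnfrsf10b (-0.92, SE 0.20) fell, while Sesn2 (1.99, SE 0.11), which senses leucine, and Rrm2b (1.05, SE 0.09), a subunit of ribonucleotide reductase, rose.

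Immediate early and dissociation stress genes rose, 8 of 21 over all genes and 9 adjusted over the list alone, with none falling (median 0.41, camera adjusted p = 0.000648, and adjusted p = 0.539 with an estimated correlation). The members with the largest rises were the transcription factors Atf3, from 8.57 ± 1.41 to 64.7 ± 12.6 CPM (2.92, SE 0.16), and Klf4, from 16.9 ± 1.87 to 81.8 ± 10.9 CPM (2.27, SE 0.12). Without control 4, the median was 0.23 and 1 member fell.

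Regional identity genes of the forebrain and midbrain were lower as a list, with 6 of 15 falling and 3 rising, the same adjusted over the list alone (median -0.40, camera adjusted p = 0.0148, and adjusted p = 0.431 with an estimated correlation). Lhx2 fell from 8.08 ± 1.54 to 1.13 ± 0.279 CPM and Barhl2 from 6.37 ± 2.37 to 2.45 ± 0.707 CPM (-1.42, SE 0.28). The median was -0.19 without KO-labelled 1, -0.25 without KO-labelled 4 and -0.63 without KO-labelled 3, and the list did not pass with voom. The 3 rises became 1 without KO-labelled 4. Of 13 GABAergic and ventral forebrain genes 3 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.828), with Rxrg among those that rose (2.66, SE 0.40); 1 fell without KO-labelled 1 or KO-labelled 4. Of 26 Hox genes 3 rose and 6 fell, the same adjusted over the list alone (adjusted p = 0.828), and Hoxd10 (-2.19, SE 0.41), Hoxb13 (-1.90, SE 0.27) and Hoxa13 (-1.57, SE 0.36) were among those that fell. The Hox list had a median of 0.06, a mean of -0.12 and a test direction of Down, and leaving out any library but control 3 moved the median by over 1.5 times, to between -0.06 and 0.18. The highest CPM of any Hox gene in any library was 9.12. Of 12 glutamatergic and cortical genes 1 rose, Zbtb18 (0.39, SE 0.09), and 1 fell, the same adjusted over the list alone (adjusted p = 0.828); the fall was lost without KO-labelled 1, and 2 fell without KO-labelled 2. Of the spinal cord and motor neuron list, 3 of 23 genes could be tested.

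Among the markers of non-neural cells, the mesenchymal and muscle lists were lower in the KO-labelled libraries. Of 18 mesenchymal genes 8 fell and 2 rose, or 9 and 3 adjusted over the list alone (median -0.71, camera adjusted p = 0.0133, and adjusted p = 0.431 with an estimated correlation). Col3a1 fell from 30.4 ± 15.9 to 7.14 ± 0.905 CPM (-2.09, SE 0.27), Mgp by -3.36 (SE 0.51) and Col1a1 by -2.08 (SE 0.38), or -1.44 without control 4, whereas Twist1 rose from 0.345 ± 0.192 to 2.02 ± 0.25 CPM (2.49, SE 0.38). Of 8 skeletal muscle genes 4 fell, or 5 adjusted over the list alone (median -0.93, camera adjusted p = 0.0184, and adjusted p = 0.394 with an estimated correlation), among them Tnnt1 (-2.20, SE 0.38) and Myh8, a myosin heavy chain gene, which fell to 17.3 ± 1.91 CPM (-0.88, SE 0.13). The number of muscle genes that fell was 2 without control 3 or KO-labelled 4 and 7 without KO-labelled 2. Beside these lists, olfactory and vomeronasal receptor genes, which neural progenitors are not known to express, summed to between 68.0 and 156.6 CPM in the controls and between 31.5 and 132.5 CPM in the KO-labelled libraries.

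The endothelial list did not pass (adjusted p = 0.323), with 3 of 10 genes lower, the same adjusted over the list alone, among them the VEGF receptor gene Kdr (-1.44, SE 0.30). Its median was -0.14, and leaving out any library but control 2 moved it by over 1.5 times, to between -0.80 and -0.23. Of 11 cartilage and bone genes 1 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.828), with Col9a3 higher (1.22, SE 0.11) and Col11a1 lower (-0.95, SE 0.15). Of 8 neural crest and Schwann genes 2 rose, also adjusted over the list alone (adjusted p = 0.865), with Avil among them (1.08, SE 0.23); 1 rose without control 2, control 3 or KO-labelled 4. Of 7 choroid plexus and ependyma genes 2 rose, also adjusted over the list alone (adjusted p = 0.583), and 1 rose without control 1, control 2, control 3, KO-labelled 1, KO-labelled 2 or KO-labelled 4, and 3 without control 4. Of 5 microglial genes tested 1 rose, also adjusted over the list alone (adjusted p = 0.852), and 1 fell without KO-labelled 2. The microglial list had a median of -0.22, a mean of -0.25 and a test direction of Up, and leaving out any library but control 3 moved the median by over 1.5 times, to between -0.67 and -0.05. Of 16 erythroid genes, 4 could be tested.

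Genes of H3K27 methylation and the UTX complex moved both ways. Of 32 tested, 5 rose and 6 fell, the same adjusted over the list alone (median 0.06, camera adjusted p = 0.793). The rises included Uty on the Y chromosome (4.90) and the falls Kdm6a on the X chromosome (-0.79), and group and sex coincided in all libraries. Mtf2, a Polycomb accessory subunit, fell from 42.9 ± 5.08 to 21.4 ± 2.45 CPM (2.01-fold lower, log2 SE 0.12), Cbx2 fell by -0.79 (SE 0.18), and the 5 rises became 3 without KO-labelled 4. The median was 0.02 without control 1 and 0.04 without KO-labelled 1 or KO-labelled 4. Of 19 interferon response genes 4 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.592), with Ifit3 (1.79, SE 0.31) and Ifi44 (1.46, SE 0.29) higher and Ifit2 lower (-1.01, SE 0.21); 2 rose without KO-labelled 4 and 6 without control 4. Of 37 ribosomal protein genes 1 rose and 1 fell, and 0 did so in either direction adjusted over the list alone (median 0.01, mean 0.01, test direction Down, adjusted p = 0.828). The rise became 2 without control 1 and 0 without control 2, control 3, KO-labelled 3 or KO-labelled 4, the fall became 2 without KO-labelled 3 and 0 without control 3, KO-labelled 1 or KO-labelled 4, and each library left out moved the median by over 1.5 times, to between -0.12 and 0.10. The 13 mitochondrially encoded genes had a count of 0 in every library.

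**Figure D3:**
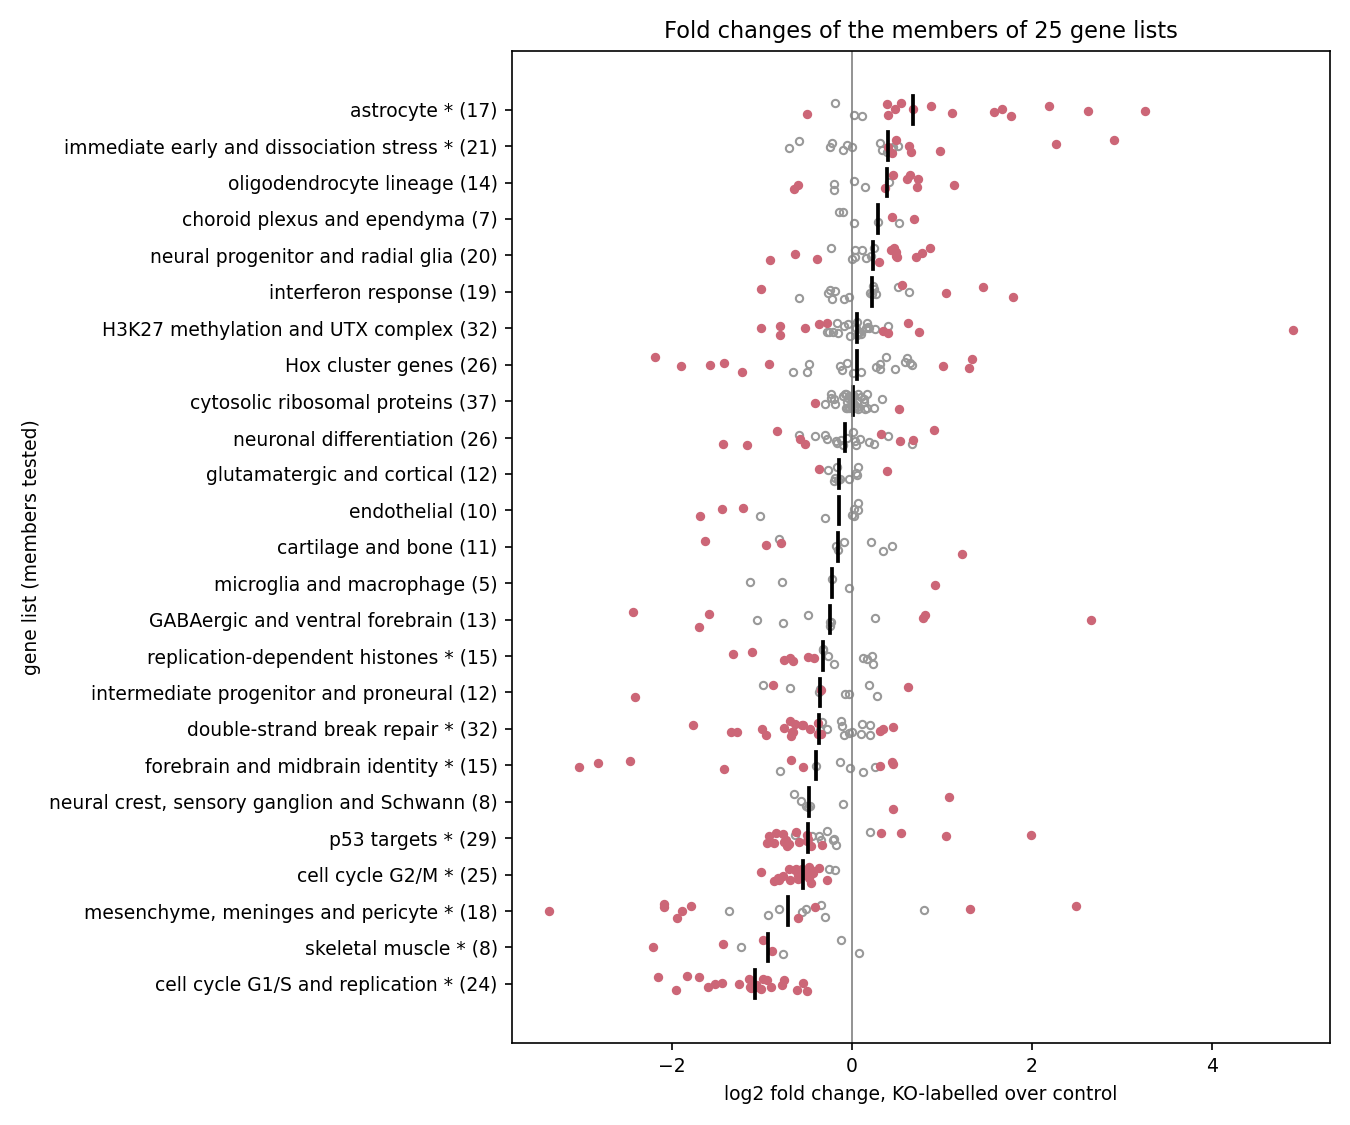
Log2 fold change (x axis, KO-labelled over control) of each tested member of 25 gene lists (y axis, members tested in parentheses; the sex-linked list is left out). Filled points passed edgeR's test, open points did not, black bars are medians and asterisks mark lists that passed camera with a preset correlation; all 24 G1/S members lie below 0.

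Across the 26 lists tested, 11 passed with the preset correlation, 3 higher and 8 lower, and 2 of these, the astrocyte and sex-linked lists, passed with an estimated correlation. By fry, the members of 14 lists moved one way on balance and those of 25 lists changed in either direction. The histone list, which passed camera with the preset correlation, did not pass fry for a move one way (fry adjusted p = 0.0633).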

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

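The tests on embryo sex, on genes that escape X inactivation, on the libraries that break the match of group and sex, and on genomic DNA as the whole of a difference were chosen only after the results were seen; the others were written down first.

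The number of genes that passed the test was far outside what other splits of the libraries gave. Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, called as many genes as the 4499 observed, and the highest of the others called 0. Every other split put libraries of both groups on each side. The group difference then widened the spread within a side, which by itself lowers the number of calls. The real split thus ranked first of 35, but the 0 calls of the others do not exclude chance. They also say nothing of embryos, which the labels do not number. The number of gene lists did not stand out, as 2 of the 35 splits, the real one included, called 11 lists. The highest of the others also called 11. It put KO-labelled 2 with controls 1, 2 and 4, so it kept a part of the group difference. Among the splits with 2 controls on each side the highest called 9 lists. The splits thus cannot decide on chance, which is not excluded for the count of lists called with a preset correlation.

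Kdm6a was lower in the KO-labelled libraries, and these had the expression of male cells while the controls had that of female cells. The probability of this complete split would be 0.00781 if each library came from a separate embryo drawn with an even chance of either sex, which the labels do not state, so whether the split arose by chance cannot be told. Kdm6a is known to escape X inactivation, and the 8 other escape genes tested had a median log2 fold change of -0.53 against -0.05 for the 526 other X-linked genes (permutation test, two-sided, p = 0.0088). This is in line with sex as a candidate explanation of the lower Kdm6a. An effect of the 53BP1 genotype on Kdm6a cannot be told apart from it, since 0 libraries had the sex of the other group.

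ATF4 targets and astrocyte genes were higher and cell cycle genes lower in the KO-labelled libraries. Of the 97 members that passed the test in the direction of the pattern, which leaves out Mt3 of the astrocyte list, which fell, 97 kept their call and direction under both RLE and upper-quartile scaling. With offsets for GC content and length 97 did so too, which argues against a GC or length trend as the whole cause. Of all genes that passed, 97.4%, 93.8% and 93.4% kept their call under these settings. The median log2 fold change of all genes was 0.0011 in the main fit, -0.013 with RLE and -0.038 with upper-quartile scaling. The calls thus did not depend on the choice among these scalings. The scalings differ too little to test an error that they share, so library composition as a cause cannot be decided. The 53BP1 genotype, embryo sex and a difference in handling or culture may each account for the pattern and cannot be told apart, because 0 libraries break the match of group and sex. The labels name both direct analysis and culture in differentiation medium and do not say which applies to a library.

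Forebrain, mesenchymal and muscle genes of low abundance fell in the KO-labelled libraries, and genomic DNA in the controls is a candidate source of their counts. Against genomic DNA as the whole difference, the median CPM of the 18 members that fell did not follow the receptor CPM within the groups (slope -0.00106, SE 0.00287, upper 95% limit 0.00632), where the difference between the groups needs a slope of 0.0908; KO-labelled 2 and 3 had 132.5 and 83.5 CPM of receptor genes and member medians of 2.31 and 2.03 CPM, against 68.0 and 6.03 in control 1. Each of the 18 had an upper limit below the slope it needs, but Neb rose with the receptor CPM within the groups (slope 0.0193, SE 0.00486, upper limit 0.0318 where 0.0381 is needed) and Col1a1 came near (0.123 where 0.148 is needed). This test replaced a comparison of the members' fold with the receptor ratio, which the choice of members by their fall made unsound. The same choice can raise the slope needed here. Narrow margins of single members, such as those of Neb and Col1a1, thus do not decide. The upper limit for the median of the members lay far below the slope needed. With the receptor covariate 13 of the 18 kept their call and 18 their sign, the median moved from -1.84 to -1.59 and calls ended as the median SE grew from 0.27 to 0.31 and folds shrank; this is below the 3 in 4 set beforehand, but 63.2% of the other genes that passed kept theirs (Fisher's exact p = 0.475), so it is no specific sign, and whether genomic DNA forms a part of the difference cannot be told. Embryo sex, handling and the 53BP1 genotype cannot be told apart here either, with 0 libraries that break the match.

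A single library stood far from the other 3 of its group in 13 of 222 groups of values, where chance gives about 1 in 20, or 11.1. Control 4 was that library in 6 of the 13, with Nrn1 at 17.3 CPM (the others between 43.3 and 46.1), Gfap at 12.1 (5.54 to 6.19), Agt at 14.9 (70.7 to 89.5), Exo1 at 81.9 (59.3 to 61.8), Col1a1 at 16.2 (4.5 to 5.21) and Alpl at 69.5 (29.1 to 30.4). Control 1 stood apart in Cox6a2 at 0.0548 CPM (0.217 to 0.259), in Zbtb18 at 50.8 CPM (56.6 to 57.7) and in the share of Gm10800 at 1.01% (2.63% to 2.92%). Control 2 had 0.109 CPM of Kdm5d where the other controls had 0. Among the KO-labelled libraries, library 2 had 209.2 CPM of Trib3 (262.2 to 268.8), library 4 had 66.7 CPM of Msi1 (43.5 to 45.6) and library 3 had 36.1 CPM of Col11a1 (51.6 to 53.6).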

How the results depend on the processing

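The removal of chromosomes X and Y, the GC and length offsets and the receptor covariate were chosen after the data were seen; the other alternatives were planned. No gene that passed the test passed it in the opposite direction under any alternative. Without 1 library at a time, 1753 to 2432 genes rose, 1497 to 2193 fell, 11 to 12 lists passed and Trp53bp1 was between -0.11 and 0.14. The balance turned with upper-quartile scaling, where 2131 genes rose and 2400 fell, and widened without a filter, to 2879 and 1754. With the receptor covariate 1573 genes rose and 1323 fell. With the Xist covariate 0 rose and 0 fell in edgeR, with 744 genes at an unadjusted p under 0.05; Xist and group had a correlation of -0.999 over the 8 libraries, the median SE grew 22.2 times and the group effect could not be estimated in practice, so no values of single genes or lists are given and other tools were not run with it. Of 105 named genes, up to 14 lost their call when 1 library was left out and 17 with the receptor covariate.

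With an estimated correlation 2 lists passed. The forebrain list lost its call with voom, its median was -0.15 with the stricter filter, the receptor covariate brought the mesenchymal median to -0.45 and the muscle median to -0.52, and the progenitor and oligodendrocyte lists passed with voom and without a filter. With the replicate number as a block 2237 genes rose and 1940 fell, and Rpl24 was the named gene to lose its call. Same-numbered libraries correlated between -0.16 and 0.28, and 4 of 8 correlated best with their own number. These 4 were the libraries numbered 1 and 2, and those numbered 3 and 4 did not. The numbers thus did not pair all libraries, and whether some are paired was left open.

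The results in this paragraph had not passed the test in either case, and the cause of the changes was not tested. Trp53bp1 changed sign, at -0.0019 with RLE, -0.0234 with upper-quartile scaling, -0.0043 with the stricter filter, -0.00088 with DESeq2 and -0.0108 with the block. For lists, the direction given by camera turned, while the median often kept its sign; the medians under the settings where it turned follow. The Hox list turned at a median of -0.0385 without a filter and 0.29 with the stricter one, and the microglial list at -0.55 without a filter, -0.83 with voom and -0.35 with the block. The ribosomal list turned at 0.0694 without a filter, the neural crest list at -0.32 with the stricter filter, and the H3K27 list at 0.0616 without the sex-linked and Y genes and 0.0602 without X and Y. The GABAergic list turned at -0.24 without X and Y and -0.13 with the receptor covariate, which also turned the neural crest list (-0.0893) and the cartilage list (0.24). Without 1 library, where the direction turned in some cases, the medians were between -0.0558 and 0.18 for the Hox, -0.67 and -0.0464 for the microglial, -0.12 and 0.097 for the ribosomal and -0.55 and -0.19 for the neural crest list. Medians changed sign with the direction kept in the neuronal list (0.00901 without a filter, 0.0937 with the receptor covariate), the cartilage list (0.0474 with the stricter filter, 0.12 without control 2), the interferon list (-0.0125 without KO-labelled 2), the endothelial list (0.000684 with the stricter filter), the Hox list (-0.0011 without control 4, -0.0546 without KO-labelled 2, -0.0558 without KO-labelled 3) and the ribosomal list, whose median of 0.01 lay below 0 with RLE, upper-quartile scaling, the stricter filter, voom, the GC and length offsets and the receptor covariate, and without control 2, control 3, control 4 or KO-labelled 3. At these depths 3 counts corresponded to between 0.126 and 0.261 CPM.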

Other observations

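The tests of ATF4 targets and of X-inactivation escape genes, and the windows of 25 and 100 genes, were chosen only after results they measure had been seen; the other lists were written after the gene results had been seen in part, though not those of their members, except Vegfa.

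Genes of cholesterol synthesis were lower in the KO-labelled libraries. Of 21 tested, 20 fell, also adjusted over the list alone, with a median log2 fold change of -1.03 (camera adjusted p = 1.18e-29, and adjusted p = 0.00451 with an estimated correlation). Idi1, an isomerase of the isoprenoid steps, fell by -1.54 (SE 0.10) and Stard4, a sterol carrier gene, by -1.39 (SE 0.11). Targets of ATF4, the transcription factor of the amino acid and integrated stress response, rose in 37 of 37 cases (median 2.36, camera adjusted p = 1.96e-138, and adjusted p = 0.00233 with an estimated correlation), the same adjusted over the list alone. Asns, which makes asparagine, rose by 2.87 (SE 0.13), the cystine transporter gene Slc7a11 by 2.73 (SE 0.11) and the cystathionase gene Cth by 3.94 (SE 0.16). This list was written after several members had been seen, so it is not independent evidence. Adm2, Fgf21, Trib3 and Chac1, among the largest rises above, are members of it. Atf3 and Sesn2 are also members of lists in the comparison above.

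Cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs and include known ATF4 targets, rose in 15 of 20 cases, or 16 adjusted over the list alone (median 1.23, camera adjusted p = 6.48e-26, and adjusted p = 0.0295 with an estimated correlation), led by Sars (2.02, SE 0.10) and Lars (1.92, SE 0.11). Of 21 glycolysis and hypoxia genes 7 rose and 1 fell, or 7 and 2 adjusted over the list alone (median 0.10, camera adjusted p = 0.00345, and adjusted p = 0.437 with an estimated correlation); Vegfa (2.81, SE 0.15), Bnip3 (1.70, SE 0.19) and Pdk1 (1.59, SE 0.17) rose and the glycolytic gene Eno1 (-0.33, SE 0.09) fell. Of 9 genes known to escape X inactivation 8 fell and 1 rose, the same adjusted over the list alone (median -0.68, camera adjusted p = 0.000429, and adjusted p = 0.0884 with an estimated correlation), among them Pbdc1 (-0.90, SE 0.10) and Eif2s3x (-0.68, SE 0.08).

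One hypothesis was that endoplasmic reticulum stress could raise the ATF4 targets, which would also raise the chaperones of that compartment. Of 19 chaperone genes 10 fell and 1, Sel1l, rose, the same adjusted over the list alone. The list had a median of -0.25 and an upper quartile of 0.03 (camera adjusted p = 0.0249, and adjusted p = 0.363 with an estimated correlation). Its members are targets of the transcription factors ATF6 and XBP1, so this argues against stress that acts through those factors. Stress that raises ATF4 targets without these chaperones was not tested. Hspa5, the main chaperone, had a log2 fold change of 0.11 (SE 0.10).

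A second hypothesis was that variants linked to the targeted allele may change genes around Trp53bp1 on chromosome 2. Of the 100 nearest tested genes, 50 on either side in the GRCm38 order, 39% passed the test against 28.4% of the other genes of the chromosome (Fisher's exact p = 0.029). Windows of 25 and of 100 genes on either side were added after this result was seen. With 25 genes on either side the share was 38% against 28.9% (Fisher's exact p = 0.203), and with 100 it was 37.5% against 27.6% (Fisher's exact p = 0.00615). Windows of 100 neighbouring autosomal genes held as many such genes in 6.53% of 11554 cases, so clusters of this size were not rare, and neighbouring genes are not independent in Fisher's test. Trib3, Chac1, Fibin and P2rx3, among the largest rises, lie on chromosome 2 too. Trib3 and Chac1 are also members of the ATF4 target list, which rose in 37 of 37 cases, as are Adm2 and Fgf21 on other chromosomes. Whether linked variants changed Trib3, Chac1, Fibin or P2rx3 was not tested.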
